A study of Apis mellifera with 10 samples.

How the data were processed

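The series compares antennae of adult honey bees after embryonic injection of a CRISPR complex against orco (orco_KO, 5 libraries) with antennae after injection of buffer (control, 5 libraries). Per the labels' protocols, RNA was isolated with a PicoPure kit, ribosomal RNA was removed with a Ribozero kit, libraries were made with a stranded TruSeq kit and all were sequenced on 1 lane of a NovaSeq from both ends. The labels call the molecule polyA RNA, while the protocol describes depletion of ribosomal RNA.

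The authors deposited raw read counts per gene, 1 table per library, with no normalization. Reads were aligned with STAR 2.7.3a, per the submitters' processing notes, and counted with featureCounts of Subread 2.0.0, per the file headers. Per the file headers, counting used strand setting 2 (reads on the reverse strand) and the whole gene span as the feature, so reads in introns count and genes with long introns gain reads that a count over exons would leave out. No option for multiply mapped reads, for reads shared by overlapping features or for fragments was set, so a read that maps to near-identical receptor copies or lies in overlapping genes on the same strand is left out, and receptor counts in tandem arrays are minimum values. There were 12337 features, of which 5 were virus genomes and 12332 were bee genes. Overlap on the same strand affected 1279 bee genes, among them Or30, pHCl, SIFR, Br-c and E74, whose counts are uncertain for that reason. Library size was taken as the sum over bee genes, without the virus features.

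Gene names came from a RefSeq gene table of the same assembly, Amel_HAv3.1, and 12325 features were matched by their exact coordinates, 830 of them with a symbol other than an LOC number. The 31 gene lists fixed before the data were examined used descriptions and symbols. The gene table holds no descriptions, so the lists rest on symbols, and members were added by symbol after the table had been read and before expression was compared. A further 6 lists were added then (antioxidant enzymes, neuropeptides and their receptors, mitochondrial genome, silk proteins, patterning transcription factors and sex determination). Lists for ionotropic receptors, sensory neuron membrane proteins, hydrocarbon synthesis, cell death, DNA damage, sensory neuron transcription factors, cilia and mechanosensory channels had no matched gene and were not analysed here. Of the 29 lists with a matched gene, 25 had at least 3 tested members and entered the list tests. The lists for glia, eye, muscle, fat body, head glands and cuticle stand for other cell types that a dissected antenna could hold. Functions of LOC genes are not stated.

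Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, and groups were compared by the quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment over 9222 genes and a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with camera and an estimated correlation, and with fry, adjusted over the 25 lists. For DESeq2 the receptor list was tested with the preranked form of camera on the Wald statistics. The share of counts on odorant receptors was compared by an exact permutation test over all splits of the libraries into 5 and 5. Means and SD of CPM use TMM-scaled library sizes. A gene without reads in a whole group was given a bound from 3 counts over that group, which covers counting error only, as reads without molecular identifiers are not independent molecules. Figures were drawn with matplotlib 3.10.9.

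The text names genes by a rule fixed before the data were examined: the target; the 10 largest changes in each direction among genes past the threshold with an average log2 CPM of at least 0 and a description other than uncharacterized, receptors left out; the 5 lower and 3 higher receptors with the smallest p, and Or11; up to 3 members with the smallest p of each other list; and Ir25a, Ir8a, Ir76b and sensory neuron membrane protein 1. As the gene table holds no descriptions, a symbol other than an LOC number was required in place of a description, which keeps most genes from being named: 1087 of the called genes have an LOC symbol and 70 another. Only 1 receptor had a positive value. Or5, Or9, Or12, Or98, Syt1, Camkii, Syx1A, nAChRa3, Cpap3-d, E75 and the LOC genes of the closing section were named after their values were seen.

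The fit was tested on simulated counts with 200 changed genes drawn from the means, dispersions and library sizes of this comparison. Among 9115 tested genes, 93.7% of genes changed 4-fold and 39.2% of genes changed 2-fold were recovered, and 5.93% of calls were unchanged genes. Changes near 2-fold were thus often missed in this simulation. Fewer genes changed there than the 1157 called in the real data, and recovery after adjustment depends on that number. No pair of libraries agreed within sampling noise: the smallest chi-square per gene between libraries was 25.8, where 1 is expected from noise. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, a surrogate variable from sva 3.50.0, leaving out each library, a replicate block and other thresholds. Thinning to the smallest library, leaving out control replicates 6 and 7 together and removing each library's trend with gene span were added after seeing the data.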

Results

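RNA was sequenced from antennae of adult honey bees (Apis mellifera) that had been injected as embryos either with a CRISPR ribonucleoprotein directed at orco or with injection buffer alone. The gene orco encodes the coreceptor that insect odorant receptors need to form a working ion channel, and it carries the symbol Or2 in the annotation. The bees were reared in the laboratory, and antennae were taken no later than 24 hours after adult emergence. There were 5 control libraries, numbered 3, 4, 5, 6 and 7, and 5 orco_KO libraries, numbered 3, 5, 9, 11 and 12. Total assigned counts ranged from 9497243 to 23453748 in control libraries and from 8577550 to 18308446 in orco_KO libraries. The mean total was 17181754 ± 5536590 (SD, n = 5) in controls and 11837300 ± 4260700 (SD, n = 5) in orco_KO, a difference within the spread between libraries (exact permutation test, two-sided p = 0.143). The labels do not say that each library came from a separate bee, so the p-values measure the spread between these libraries.

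The targeted gene was examined first in every library. Or2, at linkage group 1, positions 5723757 to 5749095 on the forward strand of Amel_HAv3.1, was present at 383 ± 82.6 CPM (counts scaled to library size; SD, n = 5) in controls and 22.9 ± 9.33 CPM (SD, n = 5) in orco_KO. Each orco_KO library lay below each control: 14.3 CPM in orco_KO replicate 3, 28.9 in replicate 5, 36.2 in replicate 9, 19.0 in replicate 11 and 16.1 in replicate 12, against 493, 306, 448, 338 and 328 CPM in control replicates 3, 4, 5, 6 and 7. The log2 fold change was -4.06 (SE 0.281; edgeR quasi-likelihood test, adjusted p = 1.0e-06), which is 16.7-fold lower. Counts cover the whole gene span including introns, so they do not show whether the remaining transcripts carry an edited sequence.

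The comparison then asked how the antennal transcriptome as a whole differed after injection against orco. Of 9222 genes tested, 736 were lower and 421 were higher in orco_KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The decreases were the larger changes: 159 of the lower genes fell at least 4-fold, against 4 higher genes that rose at least 4-fold, and the median log2 fold change was -1.36 among lower and 0.85 among higher genes. In 596 lower and 284 higher genes the groups did not overlap in any library. Over all tested genes 1034 had groups that did not overlap, where chance gives 0.794% of genes. Among protein-coding genes 680 fell and 371 rose, and among long noncoding RNAs 53 fell and 49 rose. Control replicates 6 and 7 stood apart from the other controls on the second principal component. On the first component, where the groups separate, they were the controls farthest from orco_KO (-44.8 and -49.0, other controls -27.0 to -15.1). Without both of these libraries 708 genes were lower and 200 were higher. The number of higher genes also changed when single libraries were left out, to 684 without control replicate 3, 250 without control replicate 6, 276 without control replicate 7 and 250 without orco_KO replicate 3. The Wald test of DESeq2 called 824 lower and 780 higher genes, so that the share of lower genes among calls was 51.4% in place of 63.6%.

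**Figure D1:**
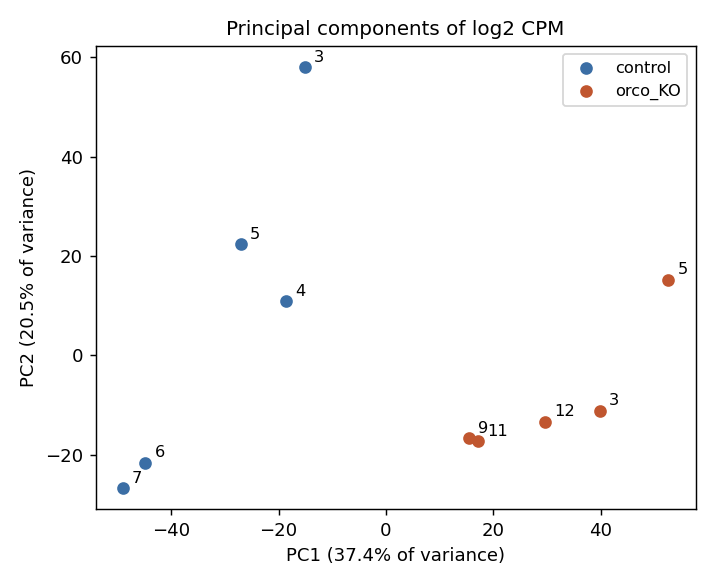
Principal components of log2 CPM over the 9222 tested genes, with 1 point per library, numbered by replicate, and the share of variance of each component on its axis. The groups separate on PC1, which holds 37.4% of the variance, and control replicates 6 and 7 have the lowest PC1 and PC2 values of the controls.

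Odorant receptors had the lowest median among the lists with at least 3 tested members. Of 29 tested receptors other than Or2, 21 fell, none rose and 8 did not pass the test (edgeR). At an unadjusted p below 0.05, 25 were lower and 1 was higher, and DESeq2 called 21 lower and 1 higher. Adjusted over the list alone, 25 fell and 1 rose. Receptor fold changes had a median of -1.98 on the log2 scale, and it was the same with the receptor absent from every orco_KO library set at its bound. Receptor reads made up 0.0167% ± 0.00298 of assigned counts in controls and 0.00667% ± 0.00290 in orco_KO (SD, n = 5 each), and every orco_KO library was below every control (exact permutation test, two-sided p = 0.00794, the smallest this design allows). All 34 receptors matched by symbol or synonym were counted in these shares. Receptors that carry only an LOC number could not be listed, so these values are not those of the whole receptor family. Of the 34, each control library held counts for 32, and orco_KO libraries held counts for 25.4 ± 3.36 (SD, n = 5).

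The receptors with the smallest p-values lay on linkage groups 2 and 12. Or30, at linkage group 2, 10057004 to 10063608, fell from 17.5 ± 1.54 to 4.39 ± 0.750 CPM (SD, n = 5; log2 fold change -1.98, SE 0.177, adjusted p = 7.1e-06). Or109, at linkage group 12, 4927844 to 4930736, fell from 12.5 ± 2.11 to 0.167 ± 0.313 CPM, with no read in 3 of the 5 orco_KO libraries (log2 fold change -6.74, SE 0.625). Of the orco_KO reads of Or109, 5 came from replicate 5 and 1 from replicate 3, and without replicate 5 the log2 fold change was -8.83. Or11, the receptor for the main component of the queen pheromone, fell from 7.92 ± 2.48 to 1.52 ± 0.283 CPM (log2 fold change -2.34, SE 0.270, adjusted p = 5.3e-05). Or26 fell by 2.36 and Or27 by 3.01 on the log2 scale. Or98 had no read in any orco_KO library and 1.13 ± 0.478 CPM (SD, n = 5) in controls, which is at least 22.2-fold lower when 3 counts over the orco_KO group are taken as the floor. Not every receptor changed. Or12 was at 15.2 ± 3.92 CPM in controls and at 13.7 CPM in orco_KO (adjusted p = 0.749), and the only receptor with a positive value was LOC100578724, listed with the synonym Or151, at 6.75 ± 1.63 against 16.7 ± 13.7 CPM (log2 fold change 1.31, SE 0.448, adjusted p = 0.0727). The value of LOC100578724 rested on single libraries: orco_KO replicate 9 was at 39.4 CPM and replicate 12 at 3.99 CPM, below every control, and the log2 fold change was 0.69 without replicate 9 (adjusted p = 0.247) and 1.59 without replicate 12 (adjusted p = 0.0135).

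The receptor list stood apart from other genes by limma's camera with a preset correlation of 0.01 (adjusted p = 3.4e-17). With an estimated correlation the adjusted p was 0.114, so the call was lost. By fry, which asks whether the members move one way, the adjusted p was 1.4e-04. Without control replicates 6 and 7, 14 of 27 tested receptors were lower.

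**Figure D2:**
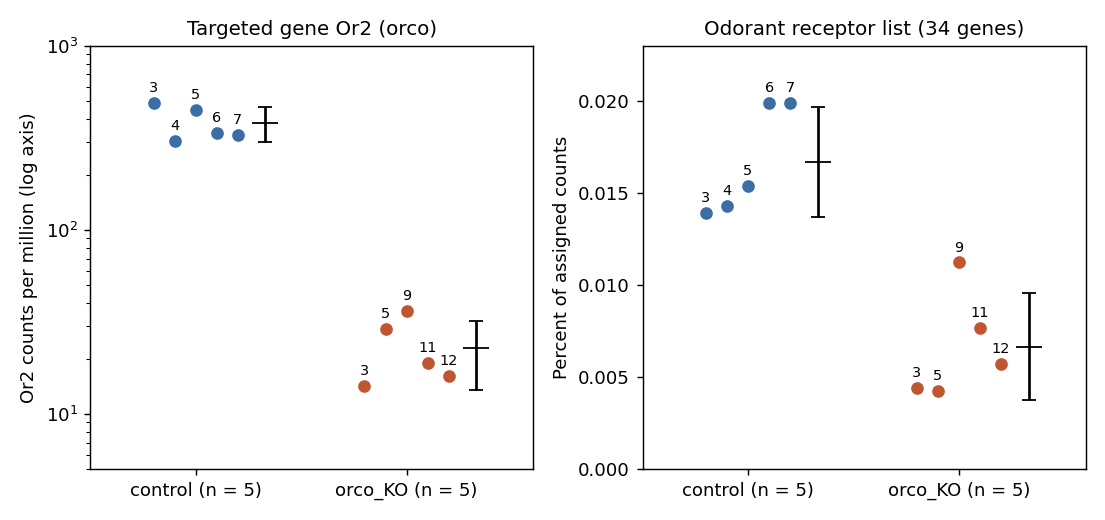
Left, Or2 in CPM on a log axis. Right, percent of assigned counts on the 34 odorant receptors; points are libraries numbered by replicate, horizontal marks are group means and bars are SD (n = 5). Control libraries hold 0.0139% to 0.0199% of counts on receptors and orco_KO libraries 0.00424% to 0.0112%.

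Most of the neuron markers fell. Of the 7 neuron markers 6 were lower, with a median log2 fold change of -1.39, and the same 6 passed when adjusted over the list alone. Nrx-1 (neurexin 1, a presynaptic adhesion protein) fell from 988 ± 152 to 246 ± 46.5 CPM (SD, n = 5; log2 fold change -2.01, SE 0.179, adjusted p = 7.1e-06). The active zone protein gene brp fell by 1.90 on the log2 scale, with 4 of 5 orco_KO libraries below all controls. Its values were 7352, 3740, 5133, 1402 and 1139 CPM in control replicates 3, 4, 5, 6 and 7. In orco_KO brp ranged from 713 to 1619 CPM, so control replicates 6 and 7 lay within that range. The calcium channel gene Cac fell by 1.62 and the sodium channel gene Para by 1.39 on the log2 scale. Syt1 and Camkii also fell. Syx1A, coding for the membrane protein syntaxin, was at 917 CPM in controls and 945 CPM in orco_KO. The list passed camera with the preset correlation (adjusted p = 1.7e-04) and fry (adjusted p = 0.00625), and not camera with an estimated correlation (adjusted p = 0.544).

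Some further genes of neural signalling fell, while others did not pass or rose. Amih, coding for a hyperpolarization-activated cation channel, fell from 1804 ± 343 to 478 ± 120 CPM (SD, n = 5; log2 fold change -1.92, SE 0.212). Of 12 synaptic receptors 3 fell (Glurb, -1.89; pHCl, -1.49; nAChRa3, -0.65 on the log2 scale) and 1 rose (mGlutR1, 0.81); adjusted over the list alone 5 fell and 2 rose. Of 7 axon guidance and adhesion genes Nrx-1 and the neuroligin gene NLG-3 fell, the latter by 1.61 on the log2 scale, and adjusted over the list alone the count was also 2. By edgeR the octopamine receptor gene Oa1 was the only one of 9 biogenic amine receptors to change (log2 fold change -1.69, with 2 of 5 orco_KO libraries below all controls), while DESeq2 called 1 lower and 2 higher, and adjusted over the list alone 1 fell and 3 rose. The SIFamide receptor gene SIFR was the only one of 5 neuropeptide and receptor genes to change (log2 fold change -1.55), also adjusted over the list alone, and this list had a median of 0.27 and a mean of -0.03. The acetylcholinesterase gene AChE-2 fell by 1.66 on the log2 scale. AChE-2 was at 262 and 266 CPM in control replicates 6 and 7 and between 569 and 961 CPM in the other controls, against 116 to 225 CPM in orco_KO. The noncoding RNA Kakusei fell by 2.20, a call lost in 5 of 10 fits that each left out 1 library (without control replicates 6 or 7 or orco_KO replicates 9, 11 or 12; adjusted p up to 0.0875), and its log2 fold change was -1.19 without control replicates 6 and 7 together. The glutamate transporter gene Eaat-2, the only glial marker matched, fell from 7.40 ± 1.07 to 0.830 ± 0.566 CPM (SD, n = 5; log2 fold change -3.09, SE 0.398).

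**Figure D3:**
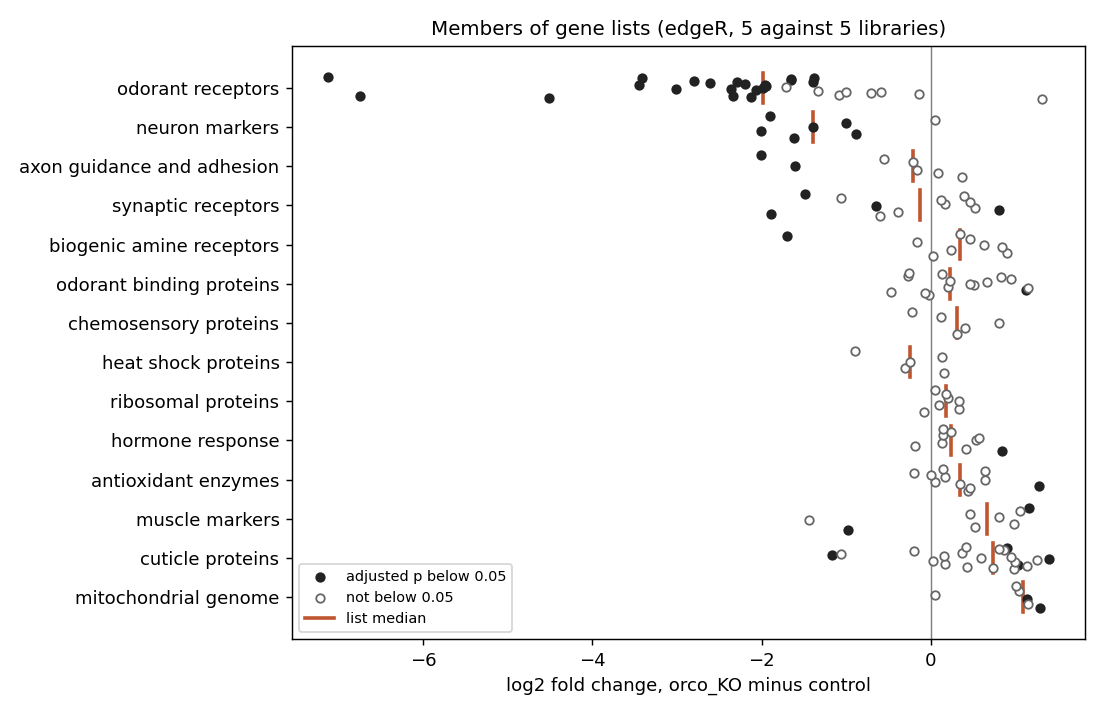
Log2 fold changes, orco_KO minus control, of the tested members of 14 gene lists; filled points have an edgeR adjusted p below 0.05, open points do not, and vertical marks are list medians. Odorant receptors (median -1.98) and neuron markers (median -1.39) lie below 0, while the mitochondrial genome list has a median of 1.09.

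Few members of other families of the antennal odorant pathway passed the test. Of 15 odorant binding proteins, soluble carriers secreted around the neurons, Obp12 rose from 11.2 ± 3.55 to 24.1 ± 14.9 CPM (SD, n = 5; edgeR adjusted p = 0.0490) and 14 did not pass with edgeR. Adjusted over the list alone the count was 0. At an unadjusted p below 0.05, 3 were higher, and DESeq2 called 2 higher. The call of Obp12 was lost in 7 of 10 fits that each left out 1 library, without control replicates 5, 6 or 7 or orco_KO replicates 3, 9, 11 or 12 (adjusted p up to 0.134), and without control replicates 6 and 7 together 1 binding protein was lower, none was higher and the list median was -0.04 in place of 0.23. None of 5 chemosensory proteins passed with edgeR, 1 was higher at an unadjusted p below 0.05 and 1 by DESeq2, and CSP3 had a log2 fold change of 0.80 (adjusted p = 0.0877). None of 6 cytochrome P450 genes passed with edgeR, 1 was higher at an unadjusted p below 0.05 and 0 by DESeq2. Of the 3 glutathione S-transferases listed as odorant degrading enzymes, GstS1 rose from 26.3 ± 7.16 to 63.8 ± 23.5 CPM (SD, n = 5; log2 fold change 1.28, SE 0.255, adjusted p = 0.00404), and by edgeR this was also the only change among 11 antioxidant enzymes, where limma-voom called 2 higher; adjusted over each list alone the count was 1 in both. The only gustatory receptor matched, Gr10, was at 1.74 CPM in controls and 2.01 CPM in orco_KO.

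Some mitochondrial and cuticle genes rose. COX2 and CYTB rose among 6 mitochondrially encoded genes, whose median log2 fold change was 1.09. Adjusted over the list alone 3 rose. These 6 were the tested part of 12 matched genes, and the median rests partly on genes with few reads. COX3, ND4 and ND5 had control means of 0.689, 1.66 and 0.414 CPM. ND1 was at 3.91 CPM in controls and 4.06 CPM in orco_KO. COX2 was at 42.6 ± 25.8 CPM in controls and 104 ± 28.3 CPM in orco_KO (SD, n = 5; log2 fold change 1.29, SE 0.344, adjusted p = 0.0241). Of 21 cuticle proteins CPR19, CPR11 and Cpap3-d rose, with log2 fold changes of 1.40, 1.03 and 0.89, and CPR3 fell by 1.16; adjusted over the list alone 6 rose and 2 fell. By camera with the preset correlation both lists had an adjusted p of 0.0224, and by camera with an estimated correlation both had an adjusted p of 0.544. The adjusted p was 0.0602 by fry for each. The calls of COX2 and CYTB depended on single libraries: the first was lost without control replicate 6 or orco_KO replicates 3 or 5 (adjusted p up to 0.0570), and the second in 7 of 10 such fits, without control replicates 3, 5, 6 or 7 or orco_KO replicates 3, 5 or 11 (adjusted p up to 0.114). Without both control replicates 6 and 7 neither gene passed, and the lists' adjusted p by camera was 0.0293 for mitochondrial and 0.00346 for cuticle genes.

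Muscle genes went both ways. TpnT (troponin T) rose from 674 ± 290 to 1511 ± 601 CPM (SD, n = 5; log2 fold change 1.17, SE 0.334, adjusted p = 0.0345), Argk (arginine kinase) fell by 0.97 on the log2 scale, and 6 of 8 muscle markers did not pass; adjusted over the list alone 4 rose and 1 fell. The TpnT call was lost in 6 of 10 fits that each left out 1 library, without control replicates 3, 6 or 7 or orco_KO replicates 3, 5 or 12 (adjusted p up to 0.0850). The blue opsin gene Blop rose by 1.57 on the log2 scale (SE 0.400, adjusted p = 0.0188), while the ultraviolet opsin gene Uvop was at 5.59 and 4.83 CPM; these were the only eye markers tested, and adjusted over the list alone 1 rose. Tg rose by 1.29 and the microRNA gene Mir6042 by 1.11 on the log2 scale, the latter losing its call without control replicate 6 or orco_KO replicate 3 (adjusted p up to 0.0581). Without control replicates 6 and 7 together the calls of TpnT, Blop, Tg, Mir6042, CPR11 and Obp12 were lost (adjusted p 0.0591 to 0.193), while GstS1 and CPR19 were called.

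Of 9 hormone response genes the ecdysone-induced transcription factor gene Br-c rose (log2 fold change 0.84, SE 0.204), also when adjusted over the list alone. E75, another ecdysone-induced gene, was at 375 and 321 CPM in control replicates 6 and 7 and between 1192 and 2186 CPM in the other controls. The clock gene Per rose by 0.53 on the log2 scale, and Cry2, the only other circadian gene, was at 28.6 and 31.2 CPM. Of 8 patterning transcription factors Eyg rose by 0.71. Per lost its call in 6 of the 10 fits that each left out 1 library, without control replicates 4, 6 or 7 or orco_KO replicates 3, 5 or 11 (adjusted p up to 0.0948), and Eyg in 8, all but those without control replicate 3 or orco_KO replicate 11 (adjusted p up to 0.112). Without control replicates 6 and 7 together the calls of Br-c (adjusted p = 0.0706), Per and Eyg were lost. Adjusted over the list alone 1 gene rose in both lists.

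No member passed in the remaining lists over all tested genes. These were 8 immune genes, 5 heat shock proteins, 7 ribosomal proteins, 8 nuclear oxidative phosphorylation genes, 5 tanning enzymes, 4 silk proteins, 4 sex determination genes, 4 fat body markers and 3 head gland and venom products. Adjusted over the list alone, 2 fat body markers were higher and the count was 0 in the others. At an unadjusted p below 0.05, 2 fat body markers, 1 ribosomal protein and 1 silk protein were higher, with the same counts by DESeq2, and by both the count was 0 in the other lists. Hex110, coding for a storage hexamerin, was at 0.681 ± 0.550 CPM in controls and 4.38 ± 6.30 CPM in orco_KO (SD, n = 5; adjusted p = 0.0595), with the largest value, 15.4 CPM, in orco_KO replicate 3. Ir25a, Ir8a, Ir76b and the sensory neuron membrane protein 1 gene were not analysed here, because no feature was matched to those names.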

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

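The tests of an equal loss across receptor neurons, of reads of Israeli acute paralysis virus, of the list differences without control replicates 6 and 7 and of the spread among members of the cuticle and mitochondrial lists were chosen only after the results were seen, and thinning and removal of the span trend were chosen after seeing the data, with their bounds set before their results.

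For the decrease of odorant receptors and neuron markers, the first pattern, the median log2 fold change over the 36 tested members was -1.93 (95% interval over genes -2.19 to -1.39). This interval and those below treat genes of the same libraries as independent, so they do not measure the spread between libraries. Lower depth of the orco_KO libraries is argued against by counts thinned to the smallest library, where the median was -1.68 (-2.03 to -1.25). With each library's trend with gene span removed it was -1.79 (-2.08 to -1.30). The 36 members pool 29 receptors with 7 longer neuron markers (median spans 1981 and 61563 bp). With the trend removed the neuron markers alone had a median of -1.45, against -1.39 in the main fit. The highest median of the 36 members under the other scalings was -1.88. A biological difference tied to orco disruption stays open as untested: counts from whole antennae do not separate fewer receptor neurons from less RNA per neuron, and the neuron marker Syx1A was at 917 CPM in controls and 945 CPM in orco_KO. The log2 fold changes of the 28 receptors with reads in both groups differed by more than their errors (Cochran's Q, chi-square p = 3.5e-38). Genes are not independent replicates. This spread cannot decide whether every class of receptor neuron was lost equally, because RNA per neuron is not separated from the number of neurons.

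Control replicates 6 and 7 are the second pattern. Their correlation across genes was 0.986, against at most 0.966 of either with another control. Depth is argued against as the cause, since after thinning to the smallest total the excess was 0.0172 (0.0163 to 0.0176 over 10 draws), where depth would take it to 0 or below. Israeli acute paralysis virus is argued against as a shared cause, since control replicate 7 held 0.0426 RPM (reads scaled to library size), less than control replicates 3, 4 and 5. Deformed wing virus stays open, at 4 and 6 reads in control replicates 6 and 7 (0.185 and 0.256 RPM) against 1, 0 and 0 reads in control replicates 3, 4 and 5, counts too few to decide, with orco_KO replicates 3, 5 and 11 at 0.219, 0.350 and 0.331 RPM; no biological explanation from the design was tested, because the labels give no group that separates these libraries.

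For the higher mitochondrial and cuticle lists, the third pattern, a smaller share of neuronal RNA would raise all other transcripts alike. For the cuticle list an equal rise of all members is argued against. Its 21 members differed from each other by more than their errors, with CPR3 at -1.16 and CPR19 at 1.40. Cochran's Q gave a chi-square p of 5.0e-13, and at most 2.6e-09 in fits without 1 library (genes are not independent replicates). This spread cannot decide whether a smaller neuronal share added to the values, because other changes could lie on top of it. The spread among the 6 mitochondrial members did not pass this test (chi-square p = 0.478, and 0.00482 to 0.748 in fits without 1 library), and for them this explanation cannot be told apart from a separate change, because the difference from the odorant binding protein list was 0.36 (SE 0.326; exact permutation test, two-sided p = 0.310), and 0.54 (SE 0.388, p = 0.214) without control replicates 6 and 7. For the cuticle list the same difference was -0.02 (SE 0.474; exact permutation test, two-sided p = 0.968), and 0.61 (SE 0.369, p = 0.161) without those libraries. The value of -0.02 lay within the bound of 0.25 set beforehand for an equal rise, and the requirement that the SE also fit within the bound was added after it was seen.

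Some libraries lay far from the others of their group, by the gap to the nearest value as a share of the group's range. The 9 cases among 188 groups of 5 values compare with 9.40 that chance alone gives. Control replicate 6 was far above the other controls in reads of 3 viruses, with 120 RPM of Israeli acute paralysis virus (share 0.990; others 0.0426 to 1.25), 0.695 of acute bee paralysis virus (share 0.848) and 9.82 of Varroa destructor virus (share 0.711). Among receptors, Or109 was low in control replicate 7 (log2 CPM 3.18, share 0.746), Or11 was high in orco_KO replicate 9 (1.10, share 0.714) and Or27 was low in orco_KO replicate 5 (-2.93, share 0.721), where it had no read. Kakusei was also without reads in orco_KO replicate 5 (share 0.824). The gene pHCl was low in control replicate 4 (log2 CPM 9.42, share 0.725) and Tsf1 was low in orco_KO replicate 11 (7.78, share 0.728).

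The counts of changed genes were larger in the real split of the libraries than in any other split drawn. Of 100 splits of the 10 libraries into 5 and 5, the real one included, 1 gave as many lower genes, 1 as many higher genes and 1 as many lower receptors, in each case the real split. For the other splits the larger of both directions was taken. The real values were 736, 421 and 21, and the highest of the other splits were 1, 1 and 0. A share of 1 in 100 is the smallest these splits can give, so chance is not excluded. Each other split mixes orco_KO with control libraries, which widens the spread within its groups and lowers its counts. The splits do not separate the injection from any other difference between the groups.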

How the results depend on the processing

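Thinning, leaving out control replicates 6 and 7 together, and removing the trend with gene span were chosen after seeing the data. The log2 fold change of Or2 and the receptor list test kept their direction and call in all 22 alternatives. Or2 ranged from -4.52, in the replicate block fit, to -3.93. The receptor share kept its direction and call in the 13 alternatives computed for it. These list tests all used the preset correlation; with an estimated correlation the receptor list's call was lost (adjusted p = 0.114). Lower receptors numbered 14 to 23. No gene called in the main comparison had the opposite sign in any alternative.

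The number of higher genes was 780 by DESeq2, 707 at an adjusted p below 0.1, 111 at an adjusted p below 0.01 and 200 without control replicates 6 and 7 together. Lower genes numbered 474 at an adjusted p below 0.01. Leaving out 1 library at a time gave 250 to 684 higher genes. For receptors called higher the range was 0 to 1, and 1 receptor was called by DESeq2, with 1 surrogate variable, with the span trend removed and at an adjusted p below 0.1, and without orco_KO replicate 12. It was LOC100578724 in each case. Lists other than the receptors past the threshold were 3 by camera with the preset correlation, 0 with an estimated correlation and 1 by fry. The neuropeptide list, up by camera, was down by fry (adjusted p = 0.491). A stricter or looser threshold changes counts by construction. Fits that each left out 1 library were of equal size, so the number of libraries does not account for the range of 250 to 684. For that range and the other changed values the cause was not tested.

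Labels share only the numbers 3 and 5 between groups and do not say that these pair bees. The correlation of deviations was 0.0793 for number 3 and 0.140 for number 5, and only number 5 correlated best with its own number. A fit with a replicate block for these numbers leaves 1 residual degree of freedom. Each other number is a block of its own, so the group difference rests on libraries 3 and 5 of each group. Its counts and adjusted p are thus not on the same footing as those from 5 against 5 libraries. In that fit 595 genes were lower and 375 higher, 15 receptors were lower, and the log2 fold change of Or2 was -4.52. Of the 1157 genes called without the block 669 were called with it, with 8 named genes losing the call (Argk, CPR11, Br-c, Blop, Kakusei, Per, Obp12 and Eyg, adjusted p 0.0544 to 0.594) and 8 gaining it (TpnCIIIa, Hex110, Ubx, Tsf1, Obp15, NLG-5, PPO and Uqcr11, adjusted p 2.9e-08 to 0.0475). In that replicate block fit some genes that did not pass in either fit changed sign: 5-ht7 -0.0817, Crzr -0.31, Hsp90 0.44, Dsx -0.0575, Dll -0.0497, Hsc70-3 0.32, Hsc70-4 0.27, Cry2 -0.38, Gr10 -0.37 and Fem -0.29.

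Other sign changes were also in genes that passed in neither fit. With 1 surrogate variable Uvop was at 0.0631 and Fem at -0.0847. Without control replicates 6 and 7 the values were Hsp90 0.025, Hsc70-4 0.0674, CSP1 -0.0269, Cry2 -0.12, Gr10 -0.45 and Fem -0.31. Leaving out 1 library gave ranges across 0: Vhdl -0.857 to 0.407, Csd -0.348 to 0.0144, AGLU2 -0.124 to 0.292, Gr10 -0.0553 to 0.836, Fem -0.0771 to 0.332, Cry2 -0.0105 to 0.302 and GstS4 -0.0634 to 0.544.

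Of 34 named genes called besides Or2, 26 were called in each fit that left out 1 library. Over 2079 comparisons of a named gene with an alternative, 1895 kept direction and side of the threshold, 88 lost the call, 67 gained it and 29 changed sign. Depth limits the low receptors: 29 of 34 passed the filter, and 24 after thinning.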

Other observations

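The test of receptor arrays was chosen only after the results were seen, and the genes named were chosen after their values were seen.

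Loci without a name inside the receptor arrays were lower along with the receptors. Between consecutive named receptors no more than 100 kb apart lie 27 protein-coding LOC genes, of which 22 were tested, 12 fell and none rose (edgeR, adjusted p below 0.05). LOC102653716, between Or107 and Or109 on linkage group 12, had no read in any orco_KO library and 2.06 CPM in controls. LOC102655180, between Or105 and Or98 on linkage group 11, was at 2.29 CPM in controls and 0.0103 CPM in orco_KO. The hypothesis that these loci are lower like the receptors predicted a median log2 fold change of -1 or below, and the median was -1.78, with 54.5% of the tested loci lower against 7.69% of other protein-coding genes. None of 10000 random lists matched on mean expression had a median as low (share 1e-04, the smallest they can give), and their lowest was -0.67. This share is not a p-value over libraries, because random genes lack the shared variation that neighbouring loci can have. For the named receptors, an estimated correlation between genes took the list's adjusted p by camera to 0.114. The lower values of the loci would go with a decrease that extends to receptor array members outside the named list. The 3 loci between Or5 and Or9 had values above 0 (LOC102655367, 1.05; LOC102655434, 0.57; LOC102655553, 0.63 on the log2 scale; none passed), while Or5 and Or9 fell.

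The gene with the smallest p of all was the long noncoding RNA LOC113218974, at linkage group 9, 9820866 to 9887529 on the forward strand. It fell from 125 ± 40.5 to 1.40 ± 0.486 CPM (SD, n = 5; log2 fold change -6.41, SE 0.299, adjusted p = 5.1e-08). On the other strand, LOC725557 overlaps it and was at 33.7 CPM in controls and 37.6 CPM in orco_KO (adjusted p = 0.617). Other unnamed loci with small p were LOC726106, LOC411519, LOC408564 and LOC413698, with log2 fold changes of -2.84, -3.03, -2.46 and -3.17. Among those that rose, LOC410747 went from 0.608 ± 0.139 to 3.48 ± 1.14 CPM (SD, n = 5) and LOC726179 from 247 ± 22.3 to 484 ± 22.9 CPM.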
